A study of Caenorhabditis elegans with 2 samples.

How the data were processed

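ChIP-seq peak lists of eGFP-tagged PROS-1 from whole late embryos of *C. elegans* strain OP500 were analysed, in 2 biological replicates of 1 group, each with the replicate number given in the labels. The authors called candidate regions, including background, for each replicate and for both alignments pooled, each with a control, and thresholded them by IDR into a single list, per the file headers and the text files deposited with them. The aligner, the peak caller, the IDR threshold and the processing of the control were not given in the sources used here. Each candidate list held 30000 regions. The lists exist in the ce10 and ce11 builds, of which the ce11 lists were annotated and the ce10 lists used only for counts and values.

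The deposited signal value of each peak is a score relative to the control with a scale that is not stated, and it was used only to rank and describe peaks within a list. The deposited significance column holds the -log10 of the q-value, and the lowest among IDR peaks was 2.47, a q-value of 0.00341. The deposited p-value column was unfilled and was not used. IDR peaks in ce11 had a full width of 324 bp in 693 cases and were narrower in 44. Read counts, alignments and signal tracks were not analysed here, so depth is unknown and intervals cover only the counting of peaks and genes.

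Annotation came from WBcel235 (the ce11 assembly) with gene models of Ensembl release 115. Each summit was assigned to 1 of 7 classes in the order promoter, 5' UTR, coding exon, 3' UTR, intron, other gene and intergenic. The promoter window ran from 1000 bp upstream to 200 bp downstream of any protein-coding transcript start, internal starts included. Replicates were compared by summits within 100 bp among as many top candidates as the IDR list holds. The class and replicate tests used 100000 rotations of all summits within each chromosome, and the chromosome test 100000 placements by chromosome length. Candidates that did not overlap an IDR peak, 29205 of them, served as a second background with Fisher's exact test.

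Gene lists (24) and motifs (18) were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives, except where the text says otherwise. A gene counted as hit when an IDR summit lay in its promoter window, and each list was compared with all other protein-coding genes. The chemoreceptor list was taken by name prefix and included 7 genes of the srf and srp series, which are not chemoreceptors. Motifs were searched on both strands in 101 bp around each summit and in 101 bp centred 300 bp to a side chosen at random, with an exact sign test on the discordant pairs. Adjusted p-values are Benjamini-Hochberg values within each family, with a threshold of 0.05.

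Genes were named by a rule with several parts. These were pros-1 and unc-119, up to 2 genes per peak with a promoter window holding 1 of the 20 strongest summits, up to 4 members of each list past the threshold, and up to 6 members with a promoter peak of the sheath glia, socket glia, excretory canal, apical matrix and ciliated neuron lists. Intergenic peaks, the neighbours drawn in the map of pros-1, F54F12.1, his-24 and the non-coding genes in the closing part were named after their values were seen.

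Alternatives covered the build, the stronger part of the list, each replicate's own top candidates in place of the IDR list, the distance that counts as shared (50 or 200 bp, or an overlap of 1 bp), other promoter windows (500 to 100 bp and 2000 to 500 bp), nearest-start assignment within 5000 bp, other backgrounds, motif windows of 51 and 201 bp and the opposite flank. Counting promoter peaks in place of genes, and the per-replicate counts at pros-1 and unc-119, were added after the data were seen.

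The tests were tested on simulated data. Of 100 sets of 737 random positions, 3 gave p under 0.05 for promoters, and planted promoter positions gave 46.0% in promoters where 46.2% were expected. With 10 ribosomal protein genes planted as hits, and with 4 of the 21 sheath glia genes, the list was called in 100 of 100 sets each. With that many planted hits the call was fixed by the counts, so it does not measure power. Fewer planted genes were not tried. Over 100 sets of random genes, drawn independently although real hits can share a peak, 1 list was called. A half-site planted in 100 of 737 windows gave an adjusted p of 2.0e-11 in the exact sign test, with 0 other motifs called. The simulated summit and flank windows had the same base composition, so motif calls that arise from a difference in composition were not tried. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.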

Results

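PROS-1 is the *Caenorhabditis elegans* member of the Prospero family of homeodomain transcription factors, known from earlier work in glia and in the excretory canal cell. The data are chromatin immunoprecipitation with sequencing (ChIP-seq), which recovers DNA bound by a protein, of an eGFP-tagged PROS-1 expressed from a transgene in whole late embryos of both sexes. There was 1 group of 2 biological replicates, numbered 1 and 2 in the labels, so no conditions were compared and the questions addressed are where the tagged protein's peaks lie and how far the replicates share them. The files analysed here give peak positions and strengths but no read totals, so the depth of each sample is unknown. Peaks that passed the authors' irreproducible discovery rate (IDR) threshold are called IDR peaks here, and the weaker regions called with them are called candidates.

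The PROS-1 peak set was small, and its strongest members lay both at protein-coding promoters, such as those of zfp-1, tasp-1 and bet-2, and in intergenic sequence. The authors' list held 737 IDR peaks on the ce11 (WBcel235) build, and the authors' signal values ran from 26.4 to 127.1 with a median of 36.4. The strongest peak, on chromosome III from 8802061 to 8802240 with a signal value of 127.1, lay within zfp-1, the worm homolog of the chromatin protein AF10, 680 bp upstream of an internal transcript start. Next among promoter peaks were those shared by tasp-1, a taspase homolog, and its neighbour K01G5.10 (III, 10759164 to 10759327, signal value 117.4), and at bet-2, which encodes a bromodomain protein (X, 10568520 to 10568824, 105.7). The second-ranked peak was intergenic (III, 13062482 to 13062685, 127.1), 7146 bp from the nearest start, that of F54F12.1.

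Other strong promoter peaks lay upstream of W06H8.6 (V, 6227579 to 6227854, signal value 105.5), between the divergent genes K06H7.7 and grp-1 (III, 8085391 to 8085714, 102.7), and upstream of the sphingomyelin synthase gene sms-2 (X, 949624 to 949789, 100.5). The summit 731 bp upstream of W06H8.6 was 191 bp from a small nucleolar RNA gene. The linker histone gene hil-7 had a peak 223 bp upstream of its start (IV, 6646010 to 6646115, 94.6), serp-1.1 a peak 321 bp upstream (X, 15841198 to 15841325, 87.2), and egg-5, which acts at egg activation, a peak 599 bp upstream (I, 4172078 to 4172242, 86.6). Ranks 19 and 20 were the promoter of rpl-3, a large-subunit ribosomal protein gene (III, 3867502 to 3867633, 85.1), and the interval between the divergent histone genes his-67 and his-68 (I, 9988904 to 9989091, 84.4).

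The replicates shared their strongest regions in part. At the zfp-1 peak, replicate 1 ranked its own summit 4 and replicate 2 ranked it 2, and the K06H7.7 and grp-1 peak was the strongest of replicate 1 and rank 28 of replicate 2. At bet-2 the ranks were 170 and 3, and at sms-2 133 and 6. Of the 737 strongest candidates of replicate 1, 271 (36.8%) had a summit within 100 bp of a summit among the 737 strongest of replicate 2. Rotating the positions within each chromosome gave a mean of 0.158% and at most 9.77% (one-sided permutation test, p = 1e-05, the smallest that 100000 rotations can give).

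The IDR list drew more on replicate 2 than on replicate 1. Among the 737 IDR peaks, 610 (82.8%) lay within 100 bp of one of the 737 strongest candidates of replicate 2 and 357 (48.4%) of one of those of replicate 1, and 279 (37.9%) met both. Across the 607 peaks matched in both candidate lists, Spearman's rho of the signal values was 0.198 and Pearson's r of their log2 values was 0.201 (permutation tests across peaks, which are not independent replicates, p = 2e-05 for each, the smallest possible). Since these peaks were selected by pooled signal, the values do not measure the agreement of the replicates over all candidates. Signal values reached 36.0 in replicate 1 and 120.5 in replicate 2. The IDR peaks were the 737 strongest candidates of the pooled alignments, without exception.

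**Figure D1:**
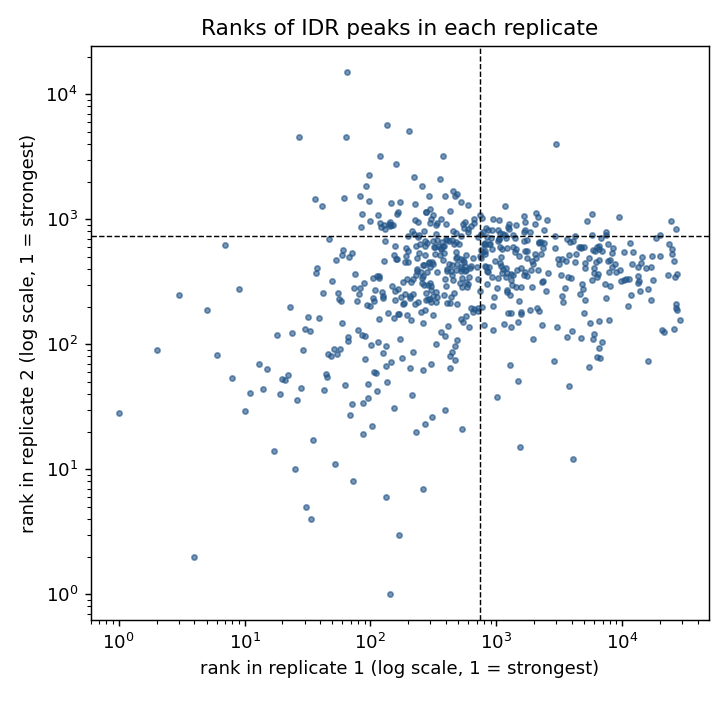
Rank of each IDR peak matched in both replicates by signal value in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale), with 1 as the strongest. Dashed lines mark rank 737, and the points spread further along the replicate 1 axis. Of all IDR peaks, 610 were within that rank in replicate 2 and 357 in replicate 1.

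PROS-1 peaks were concentrated upstream of protein-coding genes and rare in exons. The promoter window, 1000 bp upstream to 200 bp downstream of any annotated protein-coding transcript start, held 400 of 737 summits (54.3%, exact 95% interval 50.6% to 57.9%), against 25.3% ± 1.62 (SD) over rotations, a ratio of 2.14. Coding exons held 5 summits (0.678%) against 18.7% over rotations, 3' UTRs held 2 and 5' UTRs 2. Introns held 125 (16.96%) against 28.0%, intergenic sequence 166 (22.5%) against 21.97%, and non-coding or pseudogene loci 37 (5.02%) against 3.13%. Of the 400 promoter summits, 382 (95.5%) lay upstream of the nearest start, with a median position of -248.5 bp. The window itself extends mostly upstream, and the share was 73.4% of random positions in promoter windows and 70.7% of promoter candidates that did not pass (odds ratio 8.79, Fisher's exact test, p = 1.43e-35, a comparison chosen after the result was seen). In all, 172 of the 737 summits (23.3%) lay over 2000 bp from any start.

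The two-sided permutation test gave p = 2e-05 for promoters, introns, coding exons and 3' UTRs, the smallest that the rotations can give, 0.0107 for other genes, 0.750 for intergenic sequence and 0.809 for 5' UTRs (adjusted over the 7 classes, 3.5e-05 for the first 4 and 0.0150 for other genes). Among the 29205 pooled candidates that did not overlap an IDR peak, 31.0% lay in promoters (odds ratio 2.64, Fisher's exact test, p = 7.35e-38) and 21.5% in coding exons. The promoter windows rest on annotated starts, which in worms are often those of trans-spliced transcripts, and 107 promoter summits fell in the window of more than 1 gene.

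**Figure D2:**
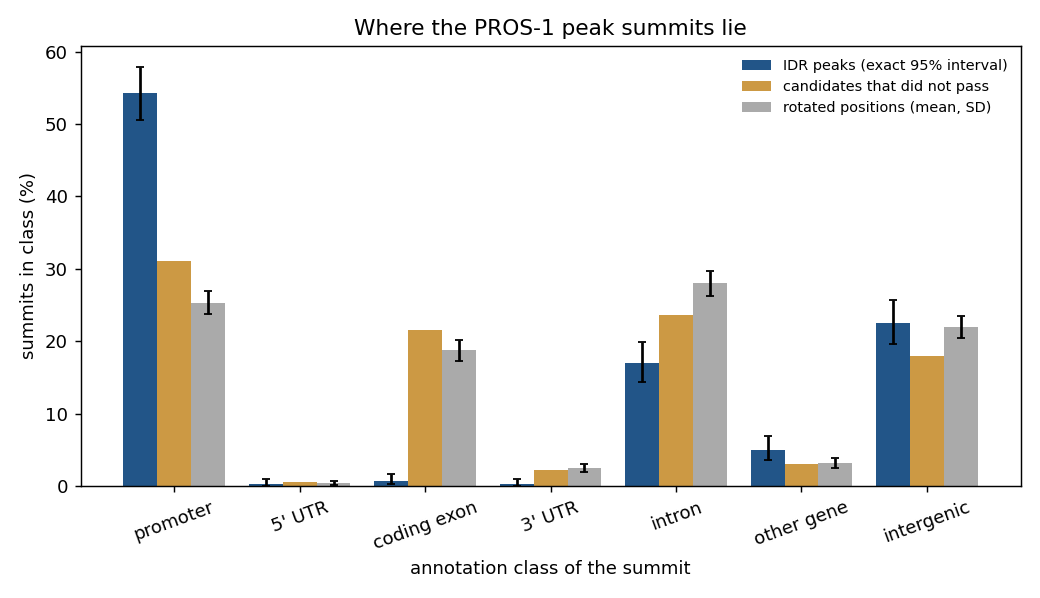
Share of summits in each annotation class, in percent, for the 737 IDR peaks (blue, exact 95% intervals), the 29205 candidates that did not pass (orange) and rotated positions (grey, mean and SD). Promoters hold 54.3% of IDR summits against 25.3% of rotated ones, and coding exons 0.678% against 18.7%.

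The X chromosome carried more PROS-1 peaks than its length gives and chromosome V fewer. The X held 185 peaks (25.1%, exact 95% interval 22.01% to 28.4%) on 17.7% of the genome, and V held 87 (11.8%) on 20.9%. Chromosome I held 139 peaks (18.9% against 15.03% of the genome), III 128 (17.4% against 13.7%), IV 100 (13.6% against 17.4%) and II 98 (13.3% against 15.2%). Strong peaks on the X included those at bet-2, sms-2 and serp-1.1.

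Random placement by chromosome length gave p = 2e-05 for X and for V (two-sided binomial test by simulation, the smallest possible, adjusted 6e-05 over the 6 chromosomes). By the same binomial test p was 0.00570 for I, 0.00626 for III, 0.00480 for IV and 0.156 for II. Each peak was placed independently, so any clustering of peaks was ignored. Against the candidates that did not pass, of which 18.3% lay on the X, the odds ratio was 1.498 (Fisher's exact test, adjusted p = 1.73e-05), and for V it was 0.597 (adjusted p = 1.49e-05). Chromosomes I, III and IV missed the threshold against this background (Fisher's exact test, adjusted p = 0.0814, 0.178 and 0.213), whereas II passed it (odds ratio 0.770, adjusted p = 0.0318). By Fisher's exact test the X share was 25% among promoter peaks, against 16.3% of promoter candidates (odds ratio 1.72, p = 1.37e-05), and 25.2% outside promoters against 19.2% (odds ratio 1.42, p = 0.00657).

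Ribosomal protein, histone and heat shock genes had PROS-1 promoter peaks more often than other genes, chemoreceptor genes less often. Across the annotation 509 of 19973 protein-coding genes (2.55%) had an IDR summit in the promoter window, against 22 of 81 ribosomal protein genes (27.2%), 11 of 50 his- genes (22%) and 5 of 19 heat shock and stress genes (26.3%). Of 1163 seven-transmembrane chemoreceptor genes, the sensory receptor families of the sr prefix, 3 had a peak (0.258%), at sre-23 (signal value 57.4), sri-5 (34.5) and srh-89 (28.0). The summit 629 bp upstream of sre-23 was 70 bp from a small nucleolar RNA gene. The summit 880 bp upstream of srh-89 was 208 bp from the start of another protein-coding gene, and the sri-5 peak also lay in another gene's window. The body wall muscle list had 4 of 32 genes (12.5%) with a peak.

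The ribosomal protein genes with the strongest peaks were rpl-3, rpl-35 (III, 7854514 to 7854837, 458 bp upstream, signal value 66.7), rpl-15 (IV, 654886 to 654979, 352 bp upstream, 66.5) and rpl-20 (IV, 4749902 to 4750225, 286 bp upstream, 59.0). Their ranks in replicates 1 and 2 were 14 and 44, 24 and 122, 30 and 133, and 9 and 277. The 11 histone genes shared 7 peaks, since several form divergent pairs. These included his-67 with his-68 and his-61 with his-62 (IV, 7486349 to 7486465, 50.4), and the list also held the linker histone gene his-24. Among chaperone genes, peaks lay at hsp-1, which encodes a cytosolic HSP70 (IV, 17278424 to 17278747, 60.2), hsp-3, a chaperone of the endoplasmic reticulum (X, 6091982 to 6092305, 57.7), hsp-90, at an internal start (V, 14685623 to 14685946, 42.5), and dnj-13, a DnaJ protein gene (II, 11545351 to 11545674, 36.3). The muscle peaks were near the lower end of the list, at unc-112 (signal value 32.1), unc-60 (30.5), an internal start of act-4 (28.2) and unc-89 (27.1). The unc-112 peak had no summit within 100 bp in the candidates of either replicate, those at act-4 and unc-89 had one only in replicate 2 (ranks 515 and 716), and that at unc-60 had ranks 5407 and 487.

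Fisher's exact test with Benjamini-Hochberg adjustment over 24 lists gave odds ratios of 14.9 for ribosomal protein genes (adjusted p = 1.23e-15), 11.002 for histone genes (3.22e-07), 13.8 for heat shock genes (5.47e-04), 5.50 for body wall muscle (0.0409) and 0.0936 for chemoreceptor genes (6.46e-09). With promoter peaks, which genes can share, counted in place of genes against promoter candidates that did not pass, the muscle list (adjusted p = 0.456, Fisher's exact test) and the chemoreceptor list (0.121) no longer passed. The heat shock list missed the threshold with only the nearest start assigned to each peak (Fisher's exact test, adjusted p = 0.0663, range over alternatives 3.91e-04 to 0.0663), as did the muscle list (0.0663), which also missed it with the wider promoter window (0.122). Among the top candidates of replicate 1 alone the heat shock share was 15.8% (Fisher's exact test, adjusted p = 0.0481) and 0 of 32 muscle genes had a peak.

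Gene lists of glia and of the excretory canal, where PROS-1 is known from earlier work, did not differ detectably from other genes. The same held for the apical matrix and ciliated neuron lists. The sheath glia list had 1 of 21 genes with a promoter peak (4.76%, exact 95% interval 0.120% to 23.8%), the Nemo-like kinase gene lit-1, at an internal start (III, 13717558 to 13717881, signal value 30.3). The socket glia list had 0 of 10 (upper bound 30.8%), the excretory canal list 1 of 34, the innexin gene inx-12 (I, 3759060 to 3759383, 39.2), and the apical matrix list 1 of 16, the lipocalin gene lpr-3 (X, 11057181 to 11057504, 26.4). The ciliated neuron list had 1 of 28, daf-19, which encodes the RFX transcription factor of cilia (II, 10169447 to 10169770, 45.8). For lit-1 the ranks in replicates 1 and 2 were 1252 and 831, and for inx-12 they were 2290 and 312. For lpr-3, which had rank 736 in the IDR list, they were 16976 and 413, and for daf-19 278 and 258.

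Adjusted p-values were 0.670 for sheath glia, 1 for socket glia, 0.738 for the excretory canal, 0.670 for the apical matrix and 0.727 for ciliated neurons (Fisher's exact test). By the same exact test the pan-neuronal list had 3 of 22 genes (13.6%, adjusted p = 0.0707), but it passed for the top candidates of replicate 2 alone and with only the nearest start assigned. The pharynx, intestine and epidermis lists had 0 of 17, 0 of 25 and 0 of 29 (Fisher's exact test, adjusted p = 1 for each). Lists of this size leave wide intervals.

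**Figure D3:**
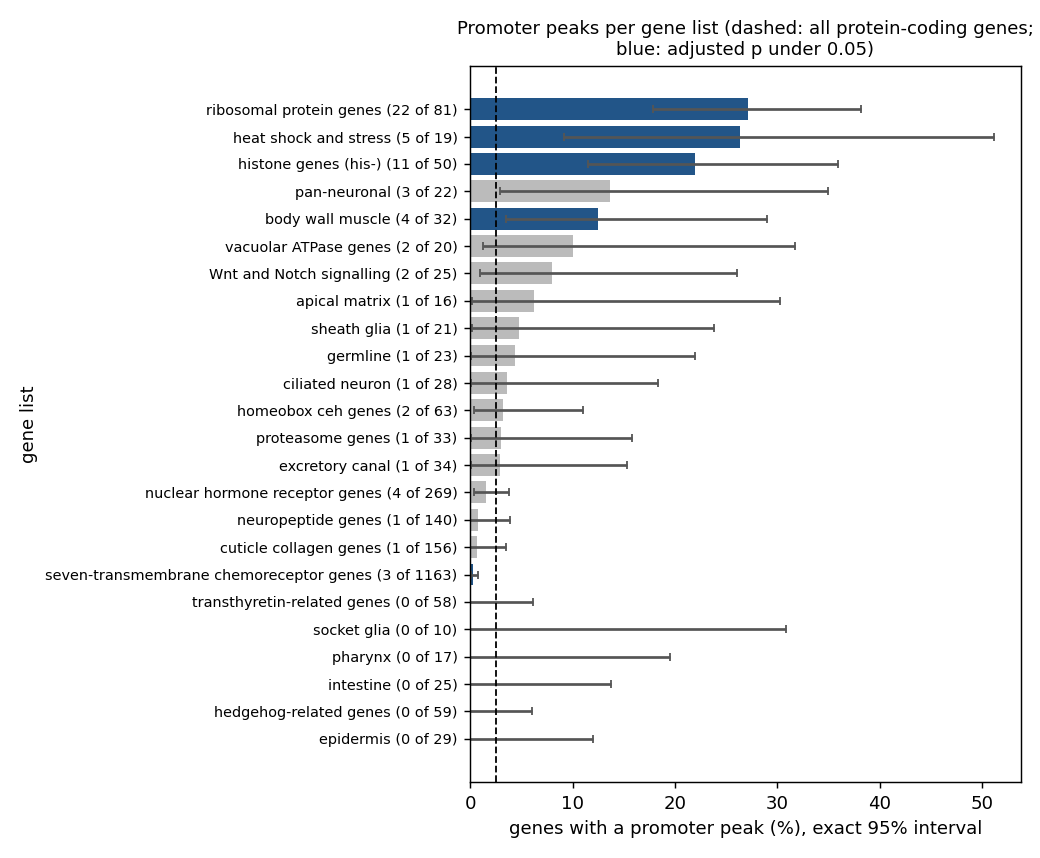
Percent of genes in each of the 24 lists with an IDR summit in the promoter window, with exact 95% intervals and the number of genes. The dashed line is the 2.55% of all protein-coding genes, blue bars had an adjusted p under 0.05, and ribosomal protein genes stand at 27.2%, chemoreceptor genes at 0.258%.

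Summits of PROS-1 peaks were rich in GAGA repeats, GC-boxes and the half-site of the Prospero family and poor in TCF, TAATTA, GATA and forkhead motifs. GAGAGAG occurred within 50 bp of 132 summits (17.9%) against 27 flanks of the same size (3.66%) centred 300 bp away, and the GC-box GGGCGG in 62 (8.41%) against 17 (2.31%). The half-site AAGRCG, as bound by the vertebrate homolog PROX1, occurred at 89 summits (12.1%) against 49 flanks (6.65%), and the forkhead-type PHA-4 motif TGTTTGC at 27 (3.66%) against 10 (1.36%). Lower at summits were the TCF motif (0.9498% against 6.11%), the homeodomain motif TAATTA (1.09% against 5.70%), GATA (0.543% against 3.93%) and the forkhead motif TRTTTAC (1.22% against 3.39%).

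The exact two-sided sign test between each summit and its flank, adjusted over 18 motifs, gave p = 6.84e-18 for GAGA, 9.53e-07 for the GC-box, 0.00171 for the half-site, 0.0196 for PHA-4, 6.28e-07 for TCF, 5.24e-06 for TAATTA, 3.93e-05 for GATA and 0.0203 for forkhead. The palindromic Prospero site occurred at 0 summits and 0 flanks, and the site defined in *Drosophila* at 18.7% against 14.8% (exact sign test, adjusted p = 0.100, range over alternatives 0.00339 to 0.703). Summits were richer in GC than candidates that did not pass, at 49.6% ± 6.21 (SD) against 39.9% ± 7.33 within 100 bp of the summit. The GC content of the flanks was not measured. Whether base composition accounts for a motif's excess was tested only for the half-site, in the closing part, and not for the other motifs. In the exact test on the 369 strongest peaks the half-site missed the threshold (adjusted p = 0.146, range over alternatives 1.55e-05 to 0.146), as did forkhead (0.146, range 8.0e-04 to 0.265), which also missed it with the narrower window (0.0794) and against candidates that did not pass (0.0510). PHA-4 missed it with flanks on the other side of each peak (exact test, adjusted p = 0.593, range 0.00426 to 0.593) and with both the narrower (0.210) and the wider window (0.173). Among the top candidates of replicate 1 alone the exact test no longer called GATA (1.76% of summits, adjusted p = 0.696), TAATTA (2.17%, 0.222) or forkhead (1.76%, 0.265). There the GC-box was at 4.48% of summits and TCF at 2.17%, both still past the threshold (exact test, adjusted p = 0.00138 for each).

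**Figure D4:**
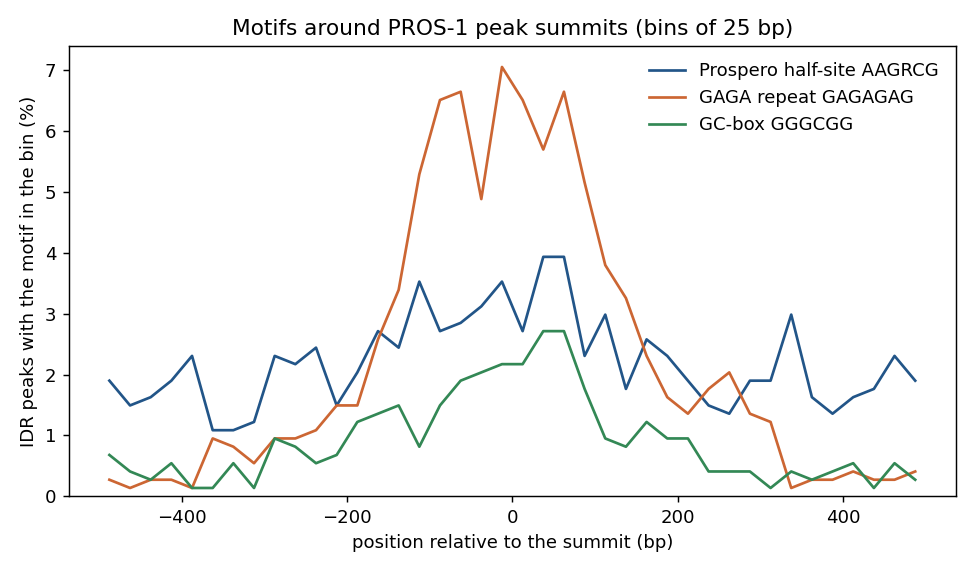
Percent of the 737 IDR peaks with a motif in each 25 bp bin, by position relative to the summit in bp, for the Prospero half-site (blue), the GAGA repeat (orange) and the GC-box (green). The GAGA repeat peaks at 7.06% of peaks in the bin just left of the summit, and the half-site and the GC-box reach at most 3.93% and 2.71%.

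Within the IDR list, peak strength was not detectably tied to promoter location. Over the whole pooled list it was, as the IDR peaks, its strongest members, had 54.3% in promoters against 31.0% of candidates that did not pass. Of the 184 strongest IDR peaks 98 (53.3%) lay in promoters and of the 184 weakest 103 (56.0%), a difference of -2.72 percentage points (Fisher's exact test, two-sided, p = 0.675). The direction turned when the candidates of either replicate alone were used, with 13.04 points for those of replicate 1 (Fisher's exact test, p = 0.0163) and 2.72 for those of replicate 2 (p = 0.676).

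PROS-1 peaks lay within its own gene, but none at unc-119. The transgene is built on pros-1 and a rescuing unc-119, so both loci can be present in extra copies. Whether extra copies also cover neighbouring genes of pros-1, such as K06H7.7 and grp-1, was not examined. Within pros-1 (III, 8067289 to 8071463, plus strand) there were 2 IDR peaks, both with summits in introns, 2164 and 2949 bp from the gene's start. The stronger (8069291 to 8069614, signal value 46.7, rank 197) covered an intronic tRNA gene at 8069405 to 8069476, and the weaker (8070076 to 8070399, 27.5) had rank 679. In replicate 1 their ranks were 268 and 1079 and in replicate 2 299 and 775, so that 1 of the 2 lay among the 737 strongest in each. At unc-119 (III, 10902641 to 10908935) the best pooled candidate was intronic and had rank 1021 (signal value 22.8).

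**Figure D5:**
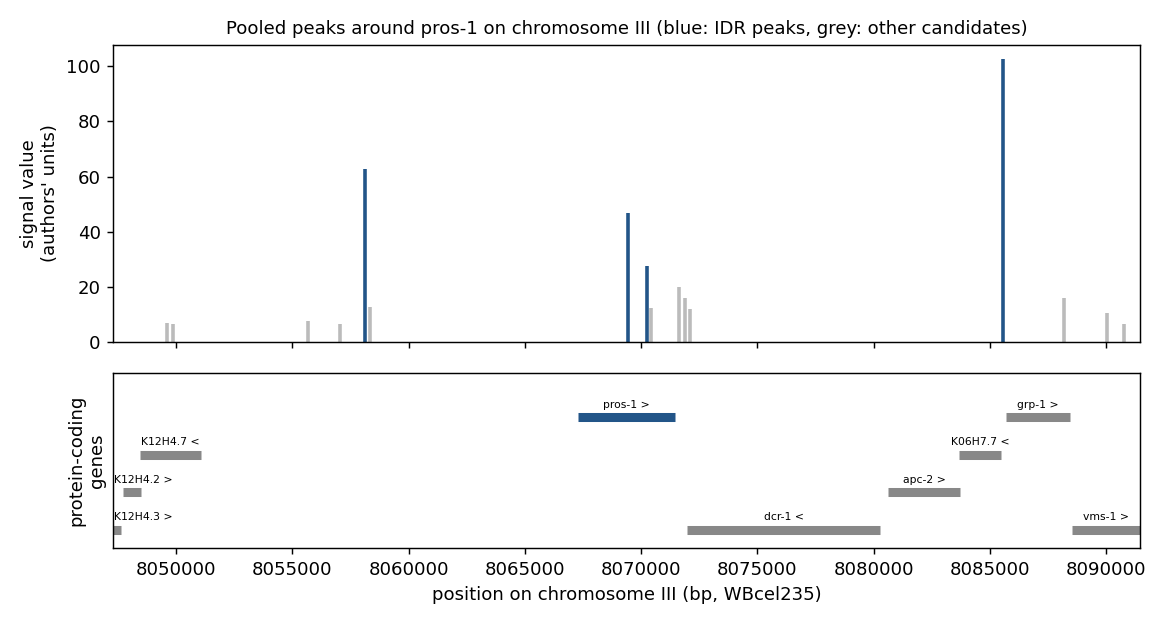
Pooled peaks and candidates in a window of 20000 bp to each side of pros-1 on chromosome III, with position in bp and height as the authors' signal value. Blue lines are IDR peaks and grey lines other candidates, and the lower panel shows protein-coding genes with arrowheads for strand. The 2 peaks inside pros-1 reach 46.7 and 27.5, and the K06H7.7 and grp-1 peak 102.7.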

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

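Counting promoter peaks in place of genes and the per-replicate counts at pros-1 were chosen only after the data were seen. The promoter share stayed above that of rotations under every alternative run, from 41.5% with the narrowest window to 69.9% with the widest. The X share stayed above its share of the genome, from 21.6% for the candidates of replicate 1 (binomial test by simulation, p = 0.00788) to 29.3% for the strongest peaks. The replicate overlap ran from 23.5% (50 bp) to 45.6% (any overlap of intervals). Ribosomal protein and histone genes passed under every alternative, with shares from 14.8% to 28.4% and from 10% to 24% of genes where all genes were the background. Both shares were lowest in the strongest part of the list, where 245 genes in all were hit, against 509. Their adjusted p was highest with the nearest start assigned, where 645 genes were hit (Fisher's exact test, 3.46e-06 at 17.3% and 0.00847 at 14%). Taking as many top pooled candidates moved nothing, since they are the IDR peaks.

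The strongest part of the list held 369 peaks by construction, and the ce10 list held 747. The number of gene lists called was 3 in place of 5 with promoter peaks as the unit against candidates that did not pass, a change of both unit and background, and 4 with only genes that have a candidate as background, where body wall muscle was also lost (Fisher's exact test, adjusted p = 0.322). It ran from 4 to 7 with a replicate left out. Lists gained were pan-neuronal and vacuolar ATPase genes without replicate 1, and pan-neuronal and Wnt and Notch genes with the nearest start. Body wall muscle genes had 0 peaks in the strongest part of the list, and from 0 to 12.5% of them had peaks with a replicate left out. Motifs called ran from 5 without replicate 2 to 9 without replicate 1, against 8, and reached 11 with windows reaching 100 bp from the summit. Motifs gained under some alternative were ETS, the *Drosophila* Prospero site, the E-box CAGCTG and the RFX half-site. ETS was gained without replicate 1, with the wider window, with the other flank and against candidates that did not pass. It was at 0.814% of summits and 3.37% of those candidates. The difference in promoter share between strong and weak peaks was -2.72 points and turned to 2.72 without replicate 1 and 13.04 without replicate 2. Of the 2 peaks at pros-1, 1 was found without replicate 1 and 1 without replicate 2. The cause was not tested for any of these. No paired analysis was possible because there is only 1 group. Unknown depth leaves open whether the smaller part of replicate 1 in the IDR list reflects fewer reads.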

Other observations

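The tests of non-coding genes and 6-base words were chosen only after the results were seen, as were those of weaker candidates at the 3 gene groups and of tRNA genes on the X. PROS-1 peaks lay at small nucleolar RNA, tRNA and snRNA genes more often than rotated positions did, and at piRNA genes and pseudogenes less often. Within 200 bp of a small nucleolar RNA gene lay 37 IDR summits against 1.35 ± 1.17 (SD) over rotations, within 200 bp of a tRNA gene 33 against 2.31 ± 1.52, and within 200 bp of a spliceosomal or spliced-leader RNA gene (the annotated snRNA class) 9 against 0.411 ± 0.649 (two-sided permutation test, p = 2e-05 for each, the smallest possible, adjusted 3e-05 over 6 classes). Of these, 14, 9 and 5 were also in a protein-coding promoter window. By the same permutation test pseudogenes had 5 against 25.6 (adjusted p = 3e-05), piRNA genes 4 against 19.5 (4.8e-05) and microRNA genes 3 against 0.923 (0.133). The top candidates of replicate 1 alone gave 30, 27 and 8 for the first 3 classes and those of replicate 2 alone 34, 29 and 8, and for pseudogenes they gave 10 and 6.

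Spliced-leader RNA genes, which supply the leader joined to downstream genes of operons, lay near 5 IDR peaks of widely different rank and were not tested as a group. The egg-5 promoter peak of rank 17 had its summit 18 bp from sls-2.4 (I, 4172206 to 4172315), and peaks of rank 23 (signal value 82.7) and 89 (61.8) lay at sls-2.2 (II, 5543598 to 5543707) and sls-2.1 (II, 5844865 to 5844974). A further peak near sls-2.4 had rank 516 (31.6), and the peak at sls-2.8 rank 549 (30.7). The peak of rank 8 (V, 12303545 to 12303710, signal value 105.4) covered the small nucleolar RNA gene C51F7.4. Of the 33 peaks near tRNA genes, 19 were on the X, where 276 of 612 annotated tRNA genes (45.1%) lie.

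Among 2080 words of 6 bases, 512 were more frequent at summits than in flanks and 416 less (exact sign test, adjusted). The 4 with the smallest p were words of A and T, lower at summits, led by AAAATT (5.56% against 39.8%) and AAAAAT (9.36% against 45.5%), a loss that went along with that of the TCF, TAATTA, GATA and forkhead motifs. Beside GAGAGA (39.8% against 8.28%), the leading higher words were CGTCTC (28.1% against 4.07%) and AGAGAC (30.1% against 5.02%). The longer word CTGCGTCTC, which ends in CGTCTC and was picked from these same summits, was found at 102 of them (13.8%), at 5 flanks (0.678%) and in 1.61% of candidates that did not pass. GACGCAG, the other strand of part of it, occurred at 123 summits (16.7%) against 7 flanks (0.9498%), at 17.5% of promoter peaks and 15.7% of the rest. In the window of 20000 bp to each side of pros-1 there were 4 IDR summits, which include the 2 peaks within pros-1 and the K06H7.7 and grp-1 peak that led to the count, where random windows held a mean of 0.323. Pooled candidates numbered 16, where random windows held a mean of 13.2.

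Ribosomal protein, histone and heat shock genes had 33 of the 400 promoter peaks (8.25%). Promoter candidates that did not pass, matched on GC content, fell in these lists in 1% of cases (Fisher's exact test, p = 6.34e-07). A like GC content thus did not place weaker candidates there as often. Since the lists were picked for their excess among IDR peaks, this comparison cannot decide whether GC content is a cause. A candidate explanation that stays open is promoters that give signal in any pulldown, and no other tagged protein was analysed here. Of the 150 genes 57.3% also had a candidate that did not pass, against 40.1% of other genes (Fisher's exact test, p = 2.52e-05). The lists differed in this. With IDR peaks counted among the candidates, the shares were 92.6% of ribosomal protein, 68.4% of heat shock and 48% of his- genes, against 41.9% of all genes. These lists were more frequent among IDR peaks than among weaker promoter candidates (95% interval of the odds ratio 5.11 to 11.5). Equal frequency was set as the mark of this explanation after the data were seen, and it was not met. The comparison cannot decide, since the lists were picked for their excess among IDR peaks. Promoters that give signal in any pulldown could also be among the strongest candidates, which the IDR peaks are. Recruitment through the Prospero half-site stays open too, as 18.2% of the 33 peaks (exact 95% interval 6.98% to 35.5%) held it against 11.7% of other promoter peaks (Fisher's exact test, p = 0.2702).

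For the excess on the X, the tables argue against GC content, GAGA repeats and tRNA genes as the whole cause. The X share was 16.3% (exact 95% interval 13.7% to 19.1%) in GC-matched candidates, below the 22.01% lower bound of the IDR share. It was 26.6% (23.1% to 30.3%) among the 605 peaks without a GAGA repeat and 23.6% (20.5% to 26.9%) among the 704 away from tRNA genes, both above the 17.7% of the genome. No biological explanation was tested, since the design has 1 group of mixed sex.

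The excess of the Prospero half-site at summits may come from base composition alone. Among 59 rearrangements of its letters that keep a CG, 61.02% had a summit-to-flank ratio at least as high as the 1.80 of the half-site (median 1.90, highest 4.24). The tables argue against overlap with GACGCAG as the cause, as 11.9% of summits against 6.65% of flanks held the half-site once that element was masked (exact sign test, p = 7.56e-04). These data therefore do not single out the half-site from other GC-rich words as a binding site of PROS-1.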
